A study of Homo sapiens with 6 samples.

How the data were processed

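The series holds 6 RNA-seq samples of A2780 ovarian cancer cells, 3 treated with DMSO and 3 with SCR-6920 at 1 µM for 48 h, grouped by the sample titles. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were made with an Illumina stranded mRNA kit, which selects polyadenylated RNA. The submitters' processing notes name HISAT2, HTSeq and the build GRCm38; their versions, the annotation and the strand setting of the counting are not given in the sources used here. GRCm38 is a mouse build, whereas 23279 of the 24054 Entrez numbers in the deposited table are in the human reference, so the build that was used is unclear and no coordinates are given.

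The authors deposited a table of raw counts per gene and a table of FPKM values. The deposited counts were whole numbers for 24054 genes, 16881 protein coding and 7173 non-coding per the file's own column; 2612 had no count in any sample. The deposited FPKM values equalled the count divided by the sample total and 1 whole-number gene length for all 21442 genes with an FPKM above 0, with a relative tolerance of 1e-06, so they hold no information beyond the counts. Totals ran from 38149448 to 39749993 counts per sample. Replicates of a group differed by more than counting noise (chi-square per gene from 3.74 to 9.25), so none appeared to be a repeat of another library.

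Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, library sizes were scaled by TMM, and a quasi-likelihood model with robust dispersion (glmQLFit, glmQLFTest) with the group as its only term was fitted to all 6 samples. All adjusted p-values of genes are Benjamini-Hochberg values over the 14233 tested genes from this edgeR test, with 0.05 as the threshold. Log2 fold changes are SCR-6920 over DMSO, and their SE was taken from the fold change and its F statistic. CPM values use the TMM-scaled library sizes. The common biological coefficient of variation was 0.0556.

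The 28 gene lists, the tests, the rule for named genes and the alternatives below were fixed before the data were examined; 659 of 667 list entries matched a symbol in the table. The 25 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The named genes were PRMT5, HIF1A, VEGFA and MDM4; the 8 largest rises and 8 largest falls among protein-coding genes with an adjusted p under 0.05, at least 5 CPM on average and no overlap of the groups; and, for each list, up to 2 members that rose and 2 that fell with the smallest p, or up to 4 each way for the HIF and angiogenic lists, 112 genes in all. Other list members named in the text (PRMT9, MDM2, FAS, XPC, ESAM and FOLR1) were chosen after their values were seen. Some genes that the rule names are not reported here.

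On counts simulated from the means and library sizes of this comparison, with 14191 genes tested, edgeR recovered 48% of genes changed 1.25-fold, 78% of those changed 1.5-fold and 90% of those changed 2-fold, and called 4 of 13969 unchanged genes. These shares are of 50 genes drawn for each fold. In the data 42% of tested genes were called, so the rates need not hold for this comparison. Alternatives were median-ratio (RLE) factors, library size only, no low-count filter, a stricter filter (a mean of 1 CPM and 10 counts in at least 3 samples), the replicate number as a block, leaving out each replicate, DESeq2 1.42.0, limma with trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, limma without that filter, fry, and an adjusted p under 0.01. HIF-1α protein and transcript isoforms were not analysed here.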

Results

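RNA sequencing measured the transcriptome of A2780 cells, an established human ovarian cancer line, after treatment with SCR-6920 at 1 µM for 48 h or with the solvent DMSO. SCR-6920 is named in the series title as an inhibitor of PRMT5, the main enzyme that places symmetric dimethyl marks on arginine residues of histones and splicing proteins. Each group held 3 samples. The deposited table held whole-number counts for 24054 genes, with totals of 39416532, 39122787 and 39749993 counts in DMSO replicates 1 to 3 and 38432635, 38642181 and 38149448 in SCR-6920 replicates 1 to 3. The labels do not say that replicates came from separate cultures, so each p-value of a gene measures only the spread between these samples, which could be technical. List p-values from camera at the preset correlation set members against other genes and take members as nearly independent. They do not measure the spread between samples.

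The comparison of SCR-6920 with DMSO asked which transcripts PRMT5 inhibition changes. Treated cells showed higher p53 target genes, led in size by the stress cytokine GDF15 and the antiproliferative gene BTG2, and lower genes of DNA replication, mitosis and homologous recombination. Of 14233 genes tested, 5976 changed at an adjusted p under 0.05 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2939 of them higher and 3037 lower. Most changes were small, with 81.4% of the changed genes under 1.5-fold, and 211 genes rose and 193 fell by 2-fold or more. As 42% of tested genes changed, a list with a similar share of changed members does not stand out by that count. The groups did not overlap for 50.6% of tested genes, against 10% by chance. The first principal component held 46.4% of the variance and separated the groups. The counts at 2-fold depended on the low-abundance genes and on the scale, with 116 higher and 103 lower under a stricter low-count filter and 21 higher and 15 lower by limma on log2(FPKM + 1).

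Among protein-coding genes with a mean of at least 5 CPM (counts scaled by library size) and no overlap of the groups, the largest rise was in GRIN2C, an NMDA receptor subunit, by 3.30 ± 0.15 on the log2 scale (SE, n = 3 per group), 9.87-fold over a DMSO level of 1.72 ± 0.41 CPM (SD, n = 3). GDF15 rose 4.33-fold (log2 2.12 ± 0.07 SE) and BTG2 3.84-fold (1.94 ± 0.04 SE). SULF2, an extracellular heparan sulfate sulfatase, rose by 2.02 ± 0.16, the inositol phosphatase gene INPP5D by 1.94 ± 0.10, and LIF, an interleukin 6 family cytokine, by 1.69 ± 0.11. INKA2 and GRIP2 had log2 changes of 1.78 and 1.75. The largest fall was in OPLAH, which encodes 5-oxoprolinase of glutathione turnover, from 19.8 ± 1.5 to 4.67 ± 0.70 CPM (SD, n = 3), a log2 change of -2.08 ± 0.12 (SE). CSPG5, PGGHG and MFSD3 followed at -1.51, -1.48 and -1.35, and the calcium channel gene ITPR3, the receptor gene FGFR3, HDHD2 and CYB561A3 lay between -1.33 and -1.29. Adjusted p-values of these 16 genes were at most 1.15e-09 (edgeR).

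**Figure D1:**
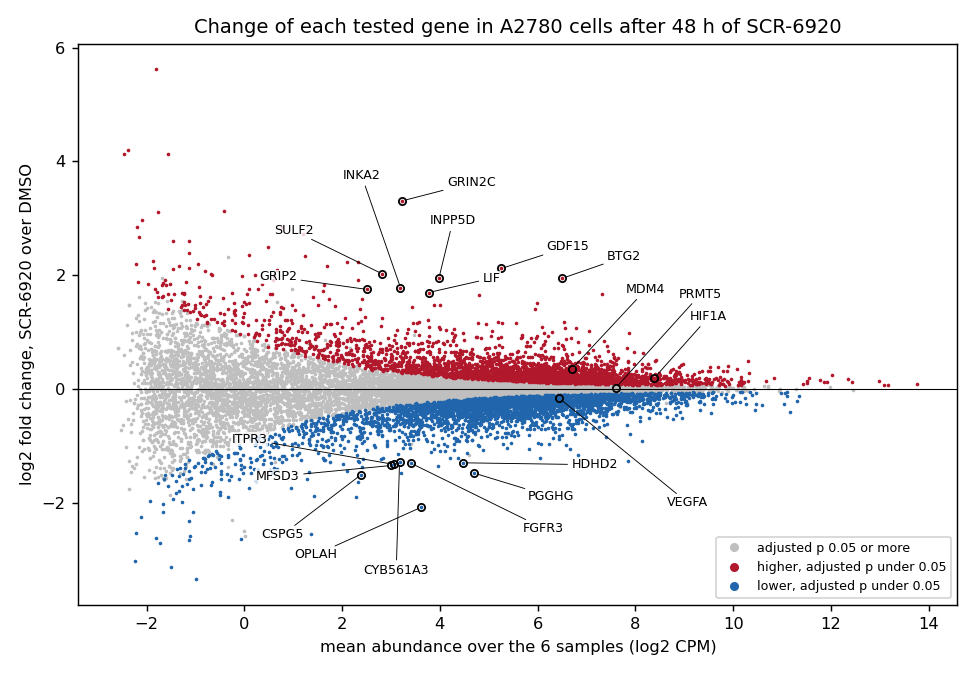
Log2 fold change of SCR-6920 over DMSO against mean abundance (log2 CPM) for the 14233 tested genes, 1 point per gene, coloured where the adjusted p (edgeR) is under 0.05. Circles mark PRMT5, HIF1A, VEGFA, MDM4 and the 8 largest rises and 8 largest falls among protein-coding genes of at least 5 CPM, from GRIN2C at 3.30 to OPLAH at -2.08.

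PRMT5 mRNA itself did not pass the test, with a log2 change of 0.02 ± 0.03 (SE, adjusted p = 0.705, edgeR). Of 14 tested genes of the PRMT family and the methylosome, PRMT1 and PRMT3 fell, both by 0.26 on the log2 scale, PRMT9 fell by 0.22, and PRMT2 alone rose, by 0.13 ± 0.05. The PRMT2 call was lost when DMSO replicate 2, SCR-6920 replicate 2 or SCR-6920 replicate 3 was left out, with adjusted p-values of 0.107, 0.0622 and 0.0951. The list had an adjusted p of 0.552 by camera, and the same genes passed when adjusted over the list alone (1 higher, 3 lower).

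The series title names loss of HIF-1α, the oxygen-regulated transcription factor subunit, and combination with the VEGF antibody bevacizumab. At the mRNA level HIF1A rose 1.14-fold (log2 0.19 ± 0.03 SE, adjusted p = 2.6e-05, edgeR), from 312 ± 17 to 355.2 ± 6.2 CPM (SD, n = 3), and VEGFA, the target of bevacizumab, fell to 0.894-fold (-0.16 ± 0.04 SE, adjusted p = 0.0031). These counts measure mRNA and not HIF-1α protein. Of 11 tested HIF pathway regulators, 6 rose and none fell. Those that rose included the HIF partner ARNT (0.16 ± 0.04) and HIF1AN (0.18 ± 0.04), an asparaginyl hydroxylase that inhibits HIF-1α. The list pools partners and inhibitors of HIF, so its count gives no direction for the pathway. The list's adjusted p was 0.206 by camera, 7 members passed when adjusted over the list alone, and 3 rose without DMSO replicate 2 and 3 without SCR-6920 replicate 2.

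Of 33 tested HIF target genes, 15 rose, 6 fell and 12 did not pass, and the same numbers passed when adjusted over the list alone. The glucose transporter gene SLC2A3 rose by 0.78 ± 0.04 on the log2 scale, the collagen prolyl hydroxylase gene P4HA2 by 0.86 ± 0.08, the histone demethylase gene KDM3A by 0.46 ± 0.04 and the mitophagy receptor gene BNIP3L by 0.42 ± 0.04. VEGFA, STC2 and the glycolytic gene TPI1 fell, the last 2 by 0.12 and 0.10. PDK1 also fell by 0.18 ± 0.07, but its call was lost without DMSO replicate 1, SCR-6920 replicate 1 or SCR-6920 replicate 3 (adjusted p of 0.31, 0.144 and 0.177). The list was higher by camera (adjusted p = 0.0094, median log2 change 0.10), a call lost at an adjusted p = 0.275 with an estimated correlation. Leaving out SCR-6920 replicate 3 lowered the number of members that fell from 6 to 3. Without the glycolysis genes, 10 of 22 members rose and 3 fell.

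Of 19 tested angiogenic factors and receptors, 6 rose and 4 fell, with the same numbers adjusted over the list alone. The VEGF family went both ways: VEGFB fell by 0.52 ± 0.07 and VEGFA by 0.16 ± 0.04, while PGF, a VEGF receptor 1 ligand, rose by 0.78 ± 0.10 (log2, SE). The coreceptor gene NRP1 rose by 0.43 ± 0.05 and ADAMTS1 by 0.32 ± 0.05. The vessel-stabilising ligand gene ANGPT1 fell by 0.60 ± 0.14 and the VEGF receptor gene FLT4 by 0.36 ± 0.10. The list's adjusted p was 0.479 by camera.

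**Figure D2:**
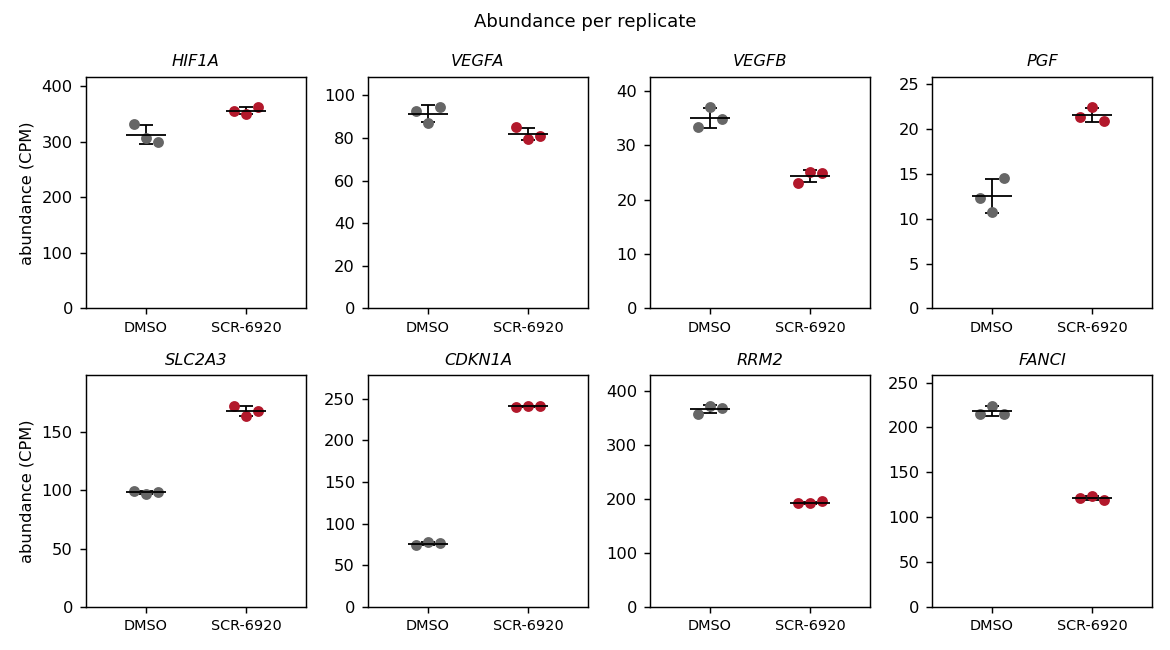
Abundance in CPM of 8 genes in each replicate of DMSO (grey) and SCR-6920 (red) samples, with group means and SD (black, n = 3); every axis starts at 0. HIF1A averaged 312 CPM in DMSO and 355.2 in SCR-6920 samples, VEGFA 91.4 and 81.8, and CDKN1A 75.9 and 240.9.

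All 29 tested p53 target genes rose, with a median log2 change of 0.85 (camera adjusted p = 9.67e-97, and adjusted p = 0.000737 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 3.17-fold (1.67 ± 0.03 SE), from 75.9 ± 2.0 to 240.9 ± 0.65 CPM (SD, n = 3). MDM2, which encodes the ubiquitin ligase of p53, rose by 0.99 ± 0.03, and the death receptor gene FAS by 1.47. The smallest rise on the list was in XPC, at 0.34. The same 29 passed when adjusted over the list alone. MDM4, a p53 inhibitor whose splicing is known to depend on PRMT5, rose at the gene level by 0.35 ± 0.04 (adjusted p = 1.3e-08, edgeR); gene counts do not separate its isoforms. Of 27 apoptosis regulators, 10 rose, among them the proapoptotic genes BAX (0.60 ± 0.03) and BBC3 (0.63 ± 0.07), and 2 fell, BOK by 0.82 ± 0.08 and CASP8 by 0.31 ± 0.06. Adjusted over the list alone the numbers were the same, and the list's adjusted p was 0.133 by camera. Fewer apoptosis genes rose without DMSO replicate 3 (6) or SCR-6920 replicate 2 (5), and without the p53 targets 8 of 25 rose and 2 fell.

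Genes of the cell cycle fell as groups. Of 32 genes of G1/S and DNA replication, 27 fell and 1 rose (camera adjusted p = 7.59e-19, and adjusted p = 0.031 with an estimated correlation), with 28 lower when adjusted over the list alone. RRM2, a ribonucleotide reductase subunit, fell to 0.527-fold (-0.92 ± 0.03 SE), and POLA1, the DNA polymerase alpha catalytic subunit, to 0.481-fold (-1.05 ± 0.05). The member that rose was PCNA, by 0.10 ± 0.03, and its call was lost without DMSO replicate 3 or SCR-6920 replicate 1 (adjusted p of 0.0859 and 0.1). Of 30 genes of G2/M and mitosis, 26 fell and none rose (6.05e-12, and adjusted p = 0.031 with an estimated correlation), with 27 lower when adjusted over the list alone. TOP2A, which encodes topoisomerase II alpha, fell by 0.51 ± 0.03 and the mitotic kinesin gene KIF20A by 0.69 ± 0.05.

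Of 31 genes of homologous recombination and Fanconi repair, 21 fell and 5 rose (camera adjusted p = 9.36e-08, and adjusted p = 0.0435 with an estimated correlation), with 22 lower and 5 higher when adjusted over the list alone. FANCI fell to 0.557-fold (-0.84 ± 0.03 SE) and the nuclease gene EXO1 by 0.70 ± 0.05, while RAD51C and RAD52 rose by 0.40 ± 0.07 and 0.53 ± 0.09. The number that rose was 3 without DMSO replicate 2 and 2 by limma on log2(FPKM + 1).

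The medians of the splicing lists were close to 0, at 0.05 on the log2 scale for SR proteins and splicing regulators and 0.04 for snRNP and Sm proteins. Of 33 SR proteins and splicing regulators, 11 rose and 5 fell, the same adjusted over the list alone. The neuronal splicing regulator gene PTBP2 rose 1.96-fold (0.97 ± 0.05 SE) and RBM39 1.43-fold (0.51 ± 0.03), while the SR protein kinase gene SRPK1 fell by 0.31 ± 0.03 and LUC7L by 0.23 ± 0.05. The list was higher by camera (adjusted p = 0.0271), but not without SCR-6920 replicate 1 (adjusted p = 0.0511), and with an adjusted p = 0.275 with an estimated correlation. Of 32 snRNP and Sm protein genes, which include known PRMT5 substrates, 15 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.0821, and 0.0402 without DMSO replicate 3). The U5 snRNP genes SNRNP200 and PRPF8 rose by 0.38 ± 0.02 and 0.34 ± 0.02, and GEMIN4 and LSM7 fell by 0.26 ± 0.04 and 0.21 ± 0.05.

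Of 30 MYC target genes, 17 fell and 6 rose (camera adjusted p = 0.00296, and adjusted p = 0.275 with an estimated correlation), with 18 lower and 7 higher when adjusted over the list alone. The nucleolar gene NOP56 fell to 0.574-fold (-0.80 ± 0.03 SE) and CAD, of pyrimidine synthesis, to 0.624-fold (-0.68 ± 0.03), while the ribosome biogenesis genes NOP2 and PES1 rose by 0.29 ± 0.03 and 0.26 ± 0.03. Of 13 tested histone genes on the replication list, 7 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0713, and 0.0383 without SCR-6920 replicate 3). H2BC12 rose by 0.89 ± 0.04 and H2BC21 by 1.62 ± 0.24. Reads from near-identical histone copies could be split between them, so these values are uncertain. H1-2 fell by 0.28 ± 0.09 and lost its call without DMSO replicate 2 or 3 or SCR-6920 replicate 3 (adjusted p of 0.0525, 0.0562 and 0.0776), leaving 1 lower each time.

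Of 22 glycolysis genes, 10 fell and 5 rose, or 11 and 6 when adjusted over the list alone (camera adjusted p = 0.552). The phosphofructokinase gene PFKL fell by 0.68 ± 0.04 and GAPDH by 0.13 ± 0.02, while SLC2A3 and PGK1 rose by 0.78 ± 0.04 and 0.12 ± 0.02. Of 30 nuclear genes of oxidative phosphorylation, 7 rose and 7 fell, or 9 and 8 when adjusted over the list alone (0.763). The complex I genes NDUFA9 and NDUFV1 changed in opposite directions, by 0.24 ± 0.04 and -0.52 ± 0.04. Of 13 transcripts encoded in mitochondrial DNA, 10 rose and none fell, or 11 when adjusted over the list alone (camera adjusted p = 0.0094, and adjusted p = 0.399 with an estimated correlation), with ND5 up by 0.24 ± 0.02. They made up 5.71, 5.90 and 5.91% of counts in the DMSO samples and 6.20, 6.19 and 6.17% in the SCR-6920 samples. Of 23 cholesterol synthesis genes, 4 rose and 6 fell, the same adjusted over the list alone (0.592), with HMGCS1 up by 0.22 ± 0.04 and MVD down to 0.466-fold. That list's median was 0.01 and its mean -0.04, so the sign differed between them, and camera gave the lower direction.

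Of 28 amino acid stress genes (ATF4 targets), 7 rose and 4 fell (camera adjusted p = 0.217), with NUPR1 and the p53 target SESN2 up by 0.78 ± 0.05 and 0.50 ± 0.03 and the serine synthesis gene PSAT1 down by 0.24 ± 0.02. Of 20 endoplasmic reticulum chaperone and unfolded protein response genes, 10 fell, among them HYOU1 (-0.50 ± 0.03) and MANF (-0.58 ± 0.04), and 4 rose, among them EDEM1 (0.72 ± 0.04). That list's adjusted p was 0.0681 by camera, and 0.0182 without DMSO replicate 1 and 0.045 without DMSO replicate 3; only 2 members rose without DMSO replicate 3, SCR-6920 replicate 1 or SCR-6920 replicate 3. Both lists gave the same numbers when adjusted over the list alone. Of 19 immediate early and heat shock genes, 4 rose, with EGR1 up by 0.45 ± 0.09, and 4 fell, with the chaperone gene HSPA8 down by 0.41 ± 0.02; 5 rose and 4 fell when adjusted over the list alone. The median (0.11) and mean (0.15) of that list were above 0 while camera gave the lower direction at an adjusted p of 0.959.

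Of 19 antigen presentation genes, 12 fell and 2 rose (camera adjusted p = 0.00296, and adjusted p = 0.175 with an estimated correlation), with 13 lower when adjusted over the list alone. HLA-E fell to 0.624-fold (-0.68 ± 0.04 SE) and HLA-C to 0.865-fold (-0.21 ± 0.02), and ERAP2 rose by 0.24 ± 0.05. The other member that rose, TAP1, lost its call without SCR-6920 replicate 2 (adjusted p = 0.0602), leaving 1 higher. Reads shared between HLA genes make their single values uncertain. Of 28 interferon response genes, 5 rose and 9 fell, the same adjusted over the list alone (0.907), with IFIT1 up 1.82-fold (0.87 ± 0.04) and IFI35 down to 0.547-fold (-0.87 ± 0.07).

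Lists of differentiation and of other cell types were not called by camera. The epithelial and mesenchymal list pools genes of both states, so its counts do not show a shift between them. Of 22 epithelial and mesenchymal genes, 10 rose and 2 fell (adjusted p = 0.0859), with VIM up by 0.19 ± 0.02, COL1A1 up by 0.94 ± 0.10 and COL6A1 down by 0.41 ± 0.07; 6 rose without DMSO replicate 2, 5 rose without SCR-6920 replicate 2, and 1 fell without DMSO replicate 3, SCR-6920 replicate 1 or SCR-6920 replicate 2. Of 9 neuronal genes, none rose and 4 fell (0.271), among them NEFH by 0.29 ± 0.03 and ENO2 by 0.49 ± 0.10; 1 rose without DMSO replicate 3 or SCR-6920 replicate 2 and 1 when adjusted over the list alone. Of 9 fibroblast markers, 4 rose and 1 fell (0.271), with PDGFRA up by 0.17 ± 0.03 and THY1 down by 0.30 ± 0.05; 2 rose without SCR-6920 replicate 3. Few markers of other cells were abundant enough to test. The endothelial marker ESAM had a log2 change of 1.01 (adjusted p = 0.177). The leukocyte marker CD68, at 3.05 CPM in DMSO samples, had a log2 change of -0.54 ± 0.22 (adjusted p = 0.0458) that did not pass without DMSO replicate 1 or 3 or SCR-6920 replicate 1 or 2 (0.105, 0.124, 0.108 and 0.139). Of 12 genes listed for ovarian epithelium and its carcinomas, the tissue of the line itself, only 2 could be tested: FOLR1 had a log2 change of 0.36 (adjusted p = 0.439) and the chromatin-remodelling gene ARID1A, which is not specific to that tissue, 0.10 (0.0126), the latter not passing without DMSO replicate 2, SCR-6920 replicate 2 or SCR-6920 replicate 3 (0.0923, 0.0623 and 0.09).

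**Figure D3:**
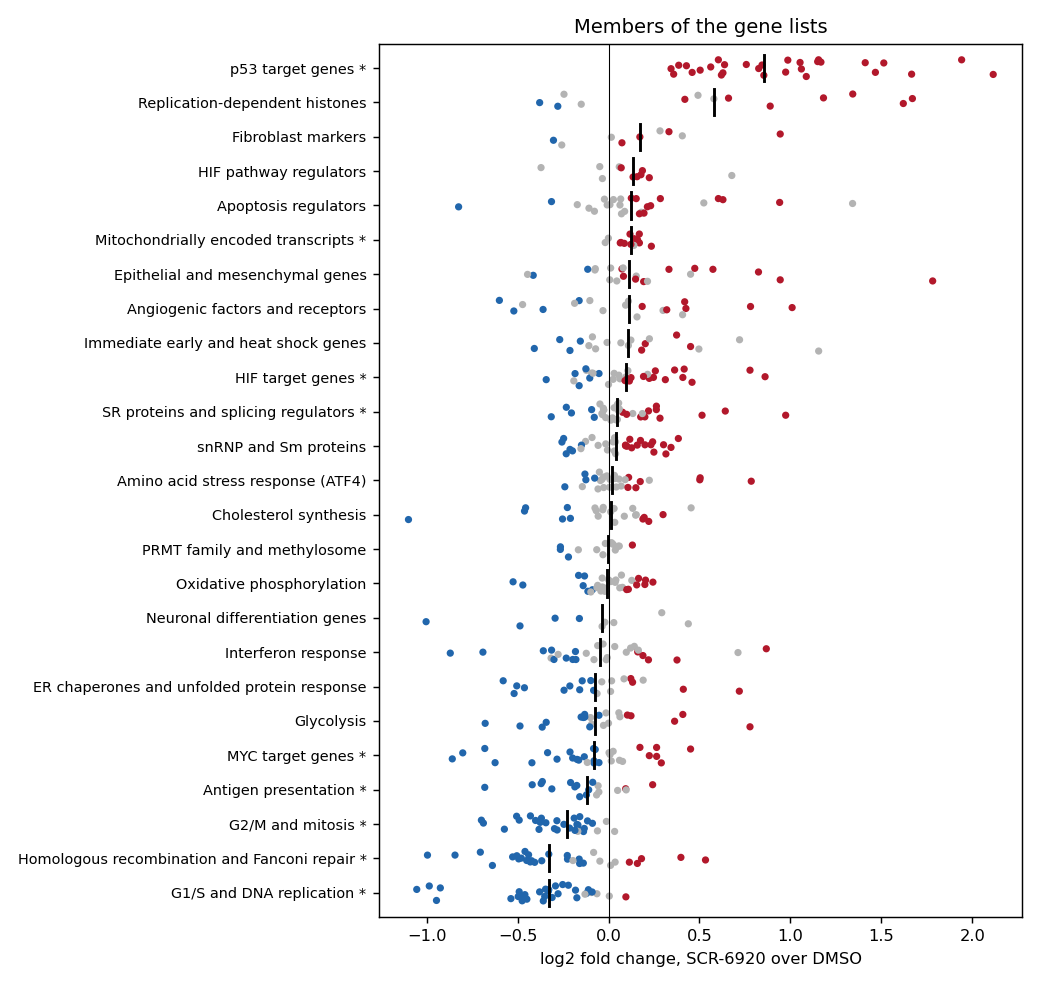
Log2 fold change of SCR-6920 over DMSO for the tested members of the 25 tested gene lists, 1 point per gene, red where it rose, blue where it fell and grey where it did not pass (adjusted p of 0.05 or more, edgeR). Black bars are list medians, from 0.85 for p53 target genes to -0.33 for G1/S and DNA replication, and a star marks the 9 lists called by camera with the preset correlation, of which 4 were called with an estimated correlation.

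The strand setting of the counting is not given in the sources used here. Of 110 named genes found in the GENCODE annotation, 52 have an annotated gene on the opposite strand, HIF1A and VEGFA included, and counts of such pairs are uncertain to that extent.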

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

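The number of changed genes stayed within 1.5 times of 5976 under all alternatives run, from 4538 at an adjusted p under 0.01 to 6144 with the replicate block, and no gene called both in a fit and in the main one changed direction. Without 1 replicate, 5190 to 5936 genes changed. Same-numbered samples did not deviate together (correlations of 0.007, 0.005 and 0.038, and, of the SCR-6920 samples, replicates 1 and 3 but not 2 correlated best with their own number), so the numbers do not pair the samples; the replicate block changed no list's call, and 1 neuronal gene rose under it against 0 without it. Genes past 2-fold depended on the filter and scale: 116 higher and 103 lower with the stricter filter, which tests fewer genes of low abundance; 21 and 15 by limma on log2(FPKM + 1), with or without its filter; and 74 and 82 on log2(FPKM + 0.1). Of the 9 lists called, 8 kept their call under the 11 other scalings, filters, blocks and left-out replicates; the SR protein list ranged from 0.00542 to 0.0511 without 1 replicate. With an estimated correlation the calls of HIF targets, SR proteins and MYC targets (each 0.275), antigen presentation (0.175) and mitochondrial transcripts (0.399) were lost. The endoplasmic reticulum list gained a call with library size only (0.047) and with no filter (0.0361), and ranged from 0.0182 to 0.109 without 1 replicate. With no filter, snRNP proteins (0.0405) and histones (0.0361) were called, and without 1 replicate they ranged from 0.0402 to 0.144 and from 0.0383 to 0.127. The immediate early list turned direction with no filter (0.968) and without DMSO replicate 3 or SCR-6920 replicate 1 or 3 (range over left-out replicates 0.553 to 0.956), never past the threshold. Fry, which does not compare a list with other genes, also called HIF regulators (0.00604), angiogenic factors (0.00366), glycolysis (0.0285), snRNP proteins (0.0177), apoptosis (0.000861), ATF4 targets (0.00308), endoplasmic reticulum (0.000861), epithelial and mesenchymal genes (0.000672), histones (0.00288), neuronal genes (0.0163) and fibroblast markers (0.00393). Apart from fry's different question and the settings whose construction is named, the cause was not tested. Of 112 named genes, 102 kept direction and side under every setting run on them, 9 lost their call at least once, and PRMT5, not called, ranged from -0.007 to 0.041 without 1 replicate. Of 56 counts of list members, 15 moved by over 1.5 times at least once. In counts simulated at this depth with 3 samples per group, edgeR recovered 78% of 1.5-fold and 90% of 2-fold changes. The simulated share of changed genes was far smaller than in the data, and depth itself was not varied.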

Other observations

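Tests of the patterns weighed here were partly chosen after the results were seen: those of scaling, of abundance, of overlapping and opposite-strand genes and of introns were, whereas those of GC content and length for the HIF and non-coding patterns and of shared list members were set down before their results. The test of Gene Ontology terms, taken from the deposited annotation column, and the genes named from it were also chosen after the data were examined. Of 3174 terms with 10 to 300 tested genes, camera called 62, 35 higher and 27 lower, and 0 with an estimated correlation (the terms quoted all at adjusted p = 0.917 or 0.918). With an estimated correlation and 6 samples, even the p53 list reached only an adjusted p of 0.000737 over 25 lists by camera. Over 3174 terms that setting could hardly call any, so its values do not decide for or against a term. Genes of the cytosolic ribosome rose, 50 of 75 with 4 lower (adjusted p = 0.000562), by a median of only 0.09 on the log2 scale, with RPS19 at 0.32 ± 0.02 (SE). Of 100 genes of the spliceosomal complex, 45 rose and 12 fell (0.00161), with the U4/U6 snRNP gene PRPF3 at 1.02 ± 0.04 and DDX46 at 0.49 ± 0.03.

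Of 20 genes of microfilament motor activity, 12 fell and 1 rose (camera adjusted p = 0.00578, and adjusted p = 0.917 with an estimated correlation), with the nonmuscle myosin gene MYH9 at -0.53 ± 0.03 (SE) and the mitochondrial myosin gene MYO19 at -0.58 ± 0.04. Of 13 genes of negative regulation of glycolysis, 7 rose and 2 fell (0.0122, and adjusted p = 0.917 with an estimated correlation), with TIGAR, a p53 target, at 0.56 ± 0.03 and STAT3 at 0.46 ± 0.04.

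Of the 10 splits of the 6 samples into 3 and 3, the real one called 5976 genes and the highest of the others 0; for lists, the real one called 9 and the highest of the others 7 (in each case 1 of the 10 splits gave as many). With 10 splits the share cannot fall under 0.05. Camera with the preset correlation thus called 3 to 7 lists in the other splits, which part the treated samples unevenly and where no gene passed.

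HIF1A mRNA and the HIF target list rose while VEGFA fell. One scaling factor shifts both genes alike, so it does not account for their log2 changes lying 0.35 ± 0.05 apart (SE). How far scaling sets each change alone stays open, since the values nearest to 0 over TMM, RLE and library size (0.17 ± 0.03 for HIF1A, -0.16 ± 0.04 for VEGFA and 0.11 for the list mean) come from scalings that put the median of all genes no further than 0.0134 from 0. The trend of change on GC content and spliced length gave 0.0038 for HIF1A, -0.0309 for VEGFA and -0.0097 for the list mean, each under 0.5 of the change by more than its SE. The test without members shared with other called lists was empty, since 0 of the 33 members were shared and the mean stayed at 0.1238. An effect of SCR-6920 on these transcripts remains a hypothesis. With an estimated correlation of 0.041, against the preset 0.01, camera lost the list call (adjusted p = 0.275). The p53 list, whose estimate was also 0.01, went from an adjusted p of 9.67e-97 to 0.000737 by camera. The loss alone thus neither shows nor excludes that the rise of the list rests on a few correlated genes.

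Non-coding genes fell more often than they rose, with 203 lower and 99 higher of 1627 tested and a median log2 change of -0.11, against 2834 and 2840 of 12606 protein-coding genes and a median of 0.01. Among them, chosen after their values were seen, the nuclear RNAs NEAT1 and MALAT1 fell by 0.88 ± 0.04 and 0.50 ± 0.05 (SE). Low abundance does not account for this, since protein-coding genes matched on abundance had a median of 0.0324 ± 0.0169 (bootstrap SE). By the RefSeq table alone (assembly GRCh38.p14), 475 non-coding genes overlapped no other gene. Their median was -0.16 ± 0.03, lower than that of all non-coding genes (-0.11). This does not exclude overlap, since GENCODE places an opposite-strand gene at some of them. In a split made after these results were seen, 123 of the 475 had an opposite-strand gene in GENCODE (median -0.24 ± 0.05), 153 had none there (0.00 ± 0.06) and 199 were not in GENCODE (-0.20 ± 0.06), while 118 genes that overlap another in RefSeq but have no opposite-strand gene in GENCODE had -0.11 ± 0.05. The 277 genes with no opposite-strand gene in GENCODE, where 936 of 1627 are annotated, had -0.0403 ± 0.045. In the 936 annotated genes the median was -0.15 before and -0.13 ± 0.02 after removal of the GC and length trend. The trend as fitted to protein-coding genes thus accounts for little of the fall in these 936 genes. A trend particular to non-coding genes was not fitted, and the annotation gap leaves the other genes untested. The 153 genes with neither a RefSeq overlap nor a GENCODE opposite-strand gene showed no fall (0.00 ± 0.06), so overlap is not excluded. Reads from overlapping or opposite-strand genes, a GC or length bias particular to non-coding genes and an effect of the compound therefore cannot be told apart.

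Protein-coding genes that fell by at least 0.5 on the log2 scale had shorter introns, with a median of 1138 bases of the per-gene median intron for 624 genes, against 1677.5 for 536 genes that rose by as much and 1868 for 11094 others. The log2 ratio of these fallen genes to all genes outside that group, those that rose included, was -0.70. It was -0.56 ± 0.09 (bootstrap SE) within 5 strata of GC content and -0.85 ± 0.14 within 5 strata of abundance, so neither accounts for most of it, although GC content may contribute a part. Spliced length also differed, with medians of 2793.5 bases for the fallen genes and 3235 for the 11094 others, and was not weighed. A candidate explanation is that PRMT5 inhibition lowers transcripts whose short introns splice poorly. Gene counts hold no intron reads, so this was not tested.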
